A study of Physcomitrium patens with 30 samples.

How the data were processed

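Total RNA was extracted with Tri-Reagent from 10-day-old protonemata, and small RNA libraries were made with the Illumina TruSeq kit and sequenced on a HiSeq instrument, per the labels' protocols. The deposited files hold counts: each lists every distinct sequence of 15 to 42 nt once with its number of reads, per the file headers and the values, and no normalization was applied. The adapter had been removed from the listed sequences and they were not aligned; the labels do not say how trimming was done. The genotype is the name in the sample title; the genotype tag of the nrpe1a samples reads nrpd1b and that of the nrpd1 samples nrpd1c. Whether these are the largest subunits of polymerases V and IV was not settled by the labels.

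The 30 samples (4 of dcl3, 2 of dcl4, 8 of mDCL, 4 of nrpe1a, 2 of nrpd1, 6 of rdr2 and 4 of rdr6) were summed by library code into 22 libraries, 8 of them with 2 runs each and 14 with 1. Runs of 1 code differed by more than sampling noise (chi-square per degree of freedom 1.53 to 1.69 in 8 pairs, over sequences with at least 20 reads in the pair) but by less than any of 35 pairs of different codes within a genotype and run type (3.78 to 49.9), and they were treated as 1 library as planned. This grouping, the comparisons, the tests, the miRNA families, the sequence groups, the rule for named sequences and most alternatives were fixed before the data were examined. Alternatives and groups added later are listed below.

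No reference genome came with the series, and the table of gene symbols that did come pairs with no value in the files. The planned unit, a cluster of reads on the genome, was therefore replaced by the distinct sequence, as the plan allowed. Reads of 18 to 28 nt were kept, which were 52.6% ± 2.89 (SD, n = 22) of all reads; longer and shorter reads were left out of the tests. A sequence was tested when it had at least 10 reads in at least 2 libraries: 117530 of 9758156 distinct sequences passed and held 90.2% ± 1.32 of the 18–28 nt reads. Counts of 13 miRNA families, each the sum of reads of 19 to 23 nt that hold the family's core sequence, entered the same fit.

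All 7 genotypes were fitted together in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, with the total of 18–28 nt reads as library size and no TMM factor, because a loss of 23–24 nt RNA in some genotypes would break TMM's assumption. The common dispersion was 0.14, with 15 residual degrees of freedom. A sequence or family was called at a Benjamini-Hochberg adjusted p under 0.05 over all features of a comparison. RPM are reads-per-million of 18–28 nt reads, given as mean ± SD over libraries; log2 changes are given with a standard error computed from the F statistic. For a sequence with no read in a genotype the fold was computed against 3 reads over that group, since its fitted change depends on the prior count.

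Length shares were taken at 20 to 24 nt, at 23–24 nt together and as the ratio of 23 to 24 nt reads (7 measures in 8 comparisons, 56 tests). They were compared with two-sided exact permutation tests of the difference in means, and over the 7 genotypes with 100000 permutations. Both were computed with NumPy 2.4.6. Groups of sequences (conserved miRNA families, 21 nt, 23–24 nt, other lengths, tRNA and rRNA fragments, and later hph) were tested with camera (preset correlation 0.01, and again with the estimated correlation) and fry in limma 3.58.1 on log2 counts-per-million with a prior count of 2, adjusted over 48 tests each. Camera compares a group with all other sequences; fry asks whether the group moves 1 way on balance and compares it with nothing else. The tRNA, rRNA and hph sequences were written down from textbook knowledge; a read counted as hph when it matched the gene on either strand without mismatch.

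For each comparison and direction, the rule named the 5 sequences with the largest absolute log2 change among those called, with a mean of at least 5 RPM and no overlap between the libraries of the groups, which gave 80; every miRNA family was named as well. A limit added later keeps RNA of other organisms out of the text: of the 80, the 32 of 20 to 24 nt with a complementary duplex partner among the reads and over 1 RPM in at least 3 genotypes are printed.

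The fit was tested on simulated counts for the 117530 sequences with the real means, library sizes and a dispersion of 0.14, with 200 sequences changed. For dcl3 against rdr6 72.7% of 8-fold, 22.4% of 4-fold and 0% of 2-fold changes were recovered, with 1 false call. For nrpd1 against rdr6 the shares were 45.5%, 5.97% and 0%, and for nrpd1 against nrpe1a 22.7%, 5.97% and 0%, with 0 false calls in each. DESeq2 recovered 66.7% of the 8-fold and 1.49% of the 2-fold changes (1 of 67) in the first of these, with 8 false calls. With so few changed sequences the adjustment is stricter than in the real fits, so these shares are not the power of the real comparisons.

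Alternatives were TMM factors, scaling to the conserved miRNA reads, DESeq2 1.42.0 with its size factors, no filter (at least 10 reads over all files), only runs whose title has the prefix Apr, every sample as its own replicate, only the genotypes compared, dcl4 in place of rdr6, each library left out in turn, and for length shares a denominator of 20–24 nt reads or distinct sequences in place of reads. Removal of hph sequences, of dcl3 1I and 1J, and of rdr2 1E and rdr6 1K were added after the data were seen. For calls of miRNA families so were scaling to the conserved miRNA reads, no filter and every sample as its own replicate, which had been planned for sequences only. Genome matches, loci between miR390 sites, repeat and gene groups, shared reads split over several places, and loci in the mutated genes were left out because they need a genome. Tables and plots were made with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 in Python 3.11.15.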

Results

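Small RNAs were sequenced from protonemata of the moss Physcomitrium patens, the filamentous stage of its life cycle, at 10 days of age. The 30 samples came from 7 mutants, each named after a gene of a small RNA pathway, and the labels gave no wild type. Runs that shared a library code were summed, which left 22 libraries: 4 each of dcl3, mDCL, rdr2 and rdr6, and 2 each of dcl4, nrpd1 and nrpe1a. DCL3, RDR2 and NRPD1 (in other plants the largest subunit of RNA polymerase IV) are known for heterochromatic siRNAs, and NRPE1 is in other plants the largest subunit of RNA polymerase V. RDR6 and DCL4 are known for trans-acting siRNAs, and mDCL is the MINIMAL DICER-LIKE protein of mosses. The 4 libraries of rdr6 served as the common comparator, so every value called higher or lower below is relative to another mutant and not to a wild type. They were also uneven: rdr6 1K and 1N differed most of the 35 pairs (chi-square per degree of freedom 49.9, Pearson r 0.75). The 22 nt share was 12.6% and 12.8% in 1K and 1L, against 16.9% and 19.5% in 1M and 1N. Their ratios of 23 to 24 nt reads were 1.57 and 1.59, against 1.95 and 2.05. The dcl3 libraries fell into pairs, 1G with 1H and 1I with 1J. Chi-square per degree of freedom was 10.9 and 14.2 within these pairs and 25.9 to 42.3 across them. The 23–24 nt share was 14.1% and 14.5% in 1G and 1H, against 17.2% and 18.7% in 1I and 1J. Tests count these as 4 separate libraries, and their p-values would be too small if each pair shares a line or culture. The names nrpd1 and nrpe1a come from the sample titles. However, the genotype tags of these samples read nrpd1c and nrpd1b, so it is not settled that they stand for polymerases IV and V. The libraries held 9712891 to 46061555 reads (mean 22130260 ± 9185067, SD, n = 22), of which 5539125 to 24569989 were 18 to 28 nt long. A single read equalled 0.0407 to 0.181 RPM (reads-per-million of 18–28 nt reads), and 3 reads over all libraries of a group were taken as the floor for a sequence without reads; these floors cover counting error only. Transcripts of the mutated genes cannot be read from small RNA libraries, so the labels could not be checked against them. The p-values below measure the spread between libraries of a genotype, which may be technical, because the labels do not say whether these came from separate lines or cultures.

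The 23 and 24 nt reads divided the genotypes most clearly. Reads of 24 nt made up 9.30% ± 0.256 (SD, n = 4) of 18–28 nt reads in mDCL and 7.30% ± 0.822 (n = 4) in rdr6, but 5.72% ± 1.06 (n = 4) in dcl3, 5.26% ± 0.318 (n = 4) in rdr2 and 5.60% ± 0.574 (n = 2) in nrpd1. Reads of 23 nt made up 9.90% ± 0.238 in mDCL, 10.4% ± 1.17 in dcl3, 11.2% ± 0.872 in rdr2, 12.03% ± 0.875 in nrpd1, 12.9% ± 0.419 in rdr6, 13.5% ± 0.162 in dcl4 and 14.4% ± 0.216 in nrpe1a. The ratio of 23 to 24 nt reads was 1.06 ± 0.0498 in mDCL, lower than in every library of the other 6 genotypes, whose means lay between 1.79 (rdr6 and dcl4) and 2.15 (nrpd1). The genotypes differed in the share of 23 nt reads, the share of 24 nt reads and their ratio (permutation test over 7 groups, p = 3e-05, 3e-05 and 4e-05, each adjusted to 9.3e-05 over 7 measures), and in the 20 nt share (adjusted permutation p = 0.0016). The shares at 21 and 22 nt were not told apart (adjusted permutation p = 0.22 and 0.051).

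**Figure D1:**
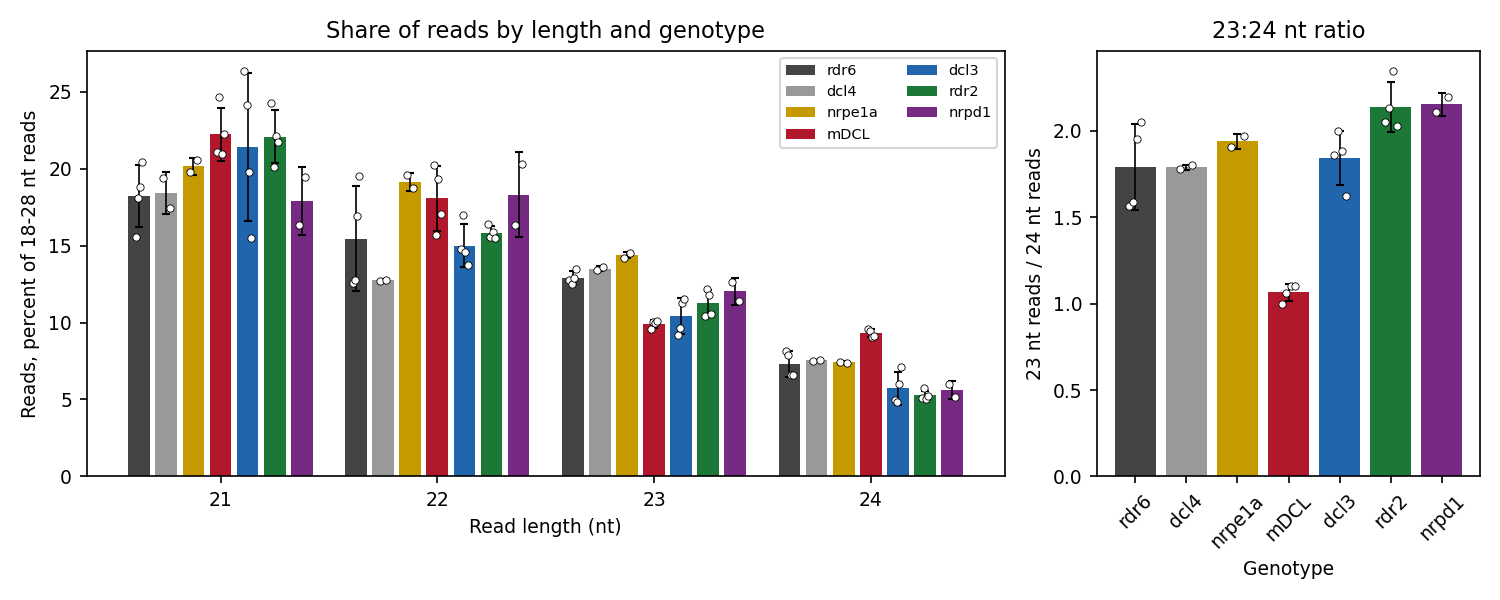
Share of 18–28 nt reads at 21 to 24 nt (left, percent) and ratio of 23 to 24 nt reads (right) in each genotype; bars are means over libraries, whiskers SD and points single libraries (n = 4 for rdr6, mDCL, dcl3 and rdr2, n = 2 for the rest). The 4 mDCL libraries lie between 0.996 and 1.10 in the ratio, below all others.

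In single pairs of genotypes, 4 libraries against 4 can give a two-sided exact permutation p no smaller than 0.0286, 4 against 2 no smaller than 0.0667 and 2 against 2 no smaller than 0.333. The dcl3 libraries did not overlap with rdr6 in the summed share of 23 and 24 nt reads (16.1% ± 2.19 against 20.2% ± 0.576, n = 4 and 4, exact p = 0.0286). Neither did rdr2 (16.5% ± 1.09, exact p = 0.0286) or mDCL (19.2% ± 0.198, exact p = 0.0286). At 24 nt alone dcl3 overlapped with rdr6 (4.83% to 7.12% against 6.58% to 8.14%, exact p = 0.0857). There rdr2 lay below rdr6 and mDCL above it without overlap (exact p = 0.0286 each), and nrpd1 lay below it (exact p = 0.133). The mDCL libraries also stood above rdr6 in the 21 nt share (22.2% ± 1.72 against 18.2% ± 2.01, exact p = 0.0286). None of the 56 pair tests passed adjustment, with 0.123 the smallest adjusted exact p. When distinct sequences were counted in place of reads, 4 differences of mDCL turned direction: those at 21, 22 and 23 nt against dcl3 and that at 22 nt against rdr6. The 23–24 nt difference of mDCL against rdr6 then shrank from -1.02 to -0.246 percentage points (exact p = 0.857). Over 20–24 nt reads as denominator, that of dcl3 against rdr6 no longer reached the smallest p (exact p = 0.114).

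Abundance was then compared sequence by sequence, over 117530 sequences with at least 10 reads in at least 2 libraries; 15539 of them were 21 nt long and 36035 were 23 or 24 nt long. A genome was not used here, so no sequence has a position or an annotated gene. Sequences are named by a rule set in advance, and those printed also had a complementary partner that would form a duplex with 2-nt overhangs and were seen above 1 RPM in at least 3 genotypes.

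The first comparison asked which small RNAs need DCL3, the Dicer-like enzyme of the heterochromatic siRNA pathway. Of the tested 24 nt sequences, 9987 (46.6%) were lower in dcl3 than in rdr6 and 158 were higher; of the 23 nt sequences 6044 were lower and 216 higher. CCAGGTACAAGAACACAGCTCACC (24 nt) and CCCAGGTACAAGAACACAGCTCA (23 nt) had no read in the 4 dcl3 libraries, against 48.3 ± 16.5 and 44.4 ± 18.2 RPM (SD, n = 4) in rdr6, and were thus at least 574-fold and 527-fold lower (adjusted p = 2.4e-12 and 2.9e-11). TGAGCTGTGTTCTTGTACCTGGGA, the 24 nt sequence complementary to them, had 1 read in dcl3 and 141 ± 45.9 RPM in rdr6 (adjusted p = 1.9e-14). These sequences overlap or are complementary and so are 1 example. Sequences that overlap them were also nearly absent from nrpe1a (below), where the read shares showed no 23–24 nt drop. Whether the dcl3 mutation or a difference between lines left these gaps was not tested. The 21 nt sequences went the other way, with 1334 higher and 430 lower. However, rdr6 itself nearly lacked 259 abundant 21 nt sequences. How many of the 1334 are among them was not tested. The split thus does not tell a gain in dcl3 from a loss in rdr6. The same limit holds for the 21 nt calls of every other genotype against rdr6. The miR533 family rose by 2.51 ± 0.37 (log2, SE) from 79.2 ± 39.5 to 451 ± 129 RPM (SD, n = 4, adjusted p = 4.6e-06).

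As groups, the 23–24 nt sequences were lower in dcl3 (camera adjusted p = 1.7e-30; adjusted p = 3.0e-05 with an estimated correlation) and the 21 nt sequences higher (1.3e-04; adjusted p = 0.0061 with an estimated correlation). The fry test, which asks only whether a group moves 1 way on balance, called both the same way (adjusted p = 1.3e-12 and 0.0032). The 21 nt group calls have the same comparator and do not tell a gain in dcl3 from a loss in rdr6. Over all lengths 18911 sequences were lower and 3758 higher. The 21 nt split was 1103 higher and 635 lower with TMM factors and 697 higher and 420 lower with DESeq2. Without libraries 1I and 1J, a pair chosen after the data were seen, 11998 sequences were lower and 2023 higher, of them 10640 and 234 at 23–24 nt and 145 and 699 at 21 nt; without 1I alone 1120 of the 21 nt sequences were called.

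The comparison of rdr2 with rdr6 asked the same of RDR2, an RNA-dependent RNA polymerase that makes the double-stranded precursors of heterochromatic siRNAs. Here 11071 of the tested 24 nt sequences were lower and 291 higher, and 6187 of the 23 nt sequences were lower and 389 higher. TATCAGCATGACAATTGGACTGC (23 nt) was absent from the 4 rdr2 libraries and had 31.5 ± 8.20 RPM in rdr6, at least 542-fold more (adjusted p = 2.4e-12). AAGACGACCGCGAGATGAAGAACC (24 nt) and ATTGTCGGAATAAACAGAAGCCT (23 nt) were at least 391-fold and 388-fold lower (adjusted p = 2.7e-12 and 4.3e-12). Of the 21 nt sequences 3283 were lower and 1433 higher, which camera, the test against all other sequences, did not call (adjusted p = 0.111, direction up), while fry found a shift down (adjusted p = 9.5e-04), as in the median of -0.14 and the mean of -0.60. The miR534 family, whose targets in moss include BLADE-ON-PETIOLE transcripts, fell by 1.31 ± 0.34 (log2, SE) from 103 ± 29.6 to 41.6 ± 14.0 RPM (n = 4, adjusted p = 0.0036).

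The 23–24 nt group was lower in rdr2 (camera adjusted p = 8.1e-23; adjusted p = 5.4e-05 with an estimated correlation), with 24603 sequences of all lengths lower and 5312 higher. The miR408 family was called higher by 3.74 ± 0.89 (adjusted p = 0.0014), but this rested on library 1E: without it the change was 0.79 (adjusted p = 0.461). Without the filter on low counts 51774 sequences were called, 31253 of them at 23–24 nt and 7426 at 21 nt.

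In nrpd1, by its title a mutant of the polymerase IV subunit, 7770 of the tested 24 nt sequences were lower than in rdr6 and 280 were higher, and 5480 of the 23 nt sequences were lower and 339 higher. TGATTTTGTTGGACCCATTGCACC (24 nt) was absent from both nrpd1 libraries and had 39.2 ± 9.74 RPM in rdr6 (n = 4), at least 235-fold more (adjusted p = 6.2e-09). The 21 nt sequences had 2369 lower and 932 higher calls. The miR171 family, which targets GRAS transcription factor transcripts, was higher by 1.17 ± 0.35 (log2, SE), at 928 ± 81.9 (n = 2) against 412 ± 180 RPM (adjusted p = 0.0164).

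The 23–24 nt group was lower in nrpd1 (camera adjusted p = 7.5e-22; adjusted p = 5.4e-05 with an estimated correlation); the 21 nt group was not called by camera (adjusted p = 0.389, direction up), while fry found a shift down (adjusted p = 9.5e-04), the sign of its median of -0.14 and mean of -0.85. Over all lengths 18344 sequences were lower and 4196 higher, and the 22540 calls became 12845 without nrpd1 library 1S and 8327 without 1T. At 23–24 nt 7474 were then lower and 438 higher without 1S and 5574 and 181 without 1T, and at 21 nt 1036 and 748, and 679 and 420. The miR171 call ended with TMM factors (log2 change 0.85, adjusted p = 0.162), with DESeq2 (0.91, adjusted p = 0.197), with these genotypes fitted alone (1.17, adjusted p = 0.0581), without 1S (1.26, adjusted p = 0.061) and without 1T (1.08, adjusted p = 0.148). In the last 3 settings the change itself stayed about as large.

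In nrpe1a, by its title a mutant of the polymerase V subunit, 1863 of the 23–24 nt sequences were lower than in rdr6 and 1736 were higher, and no drop of the kind seen in dcl3, rdr2 and nrpd1 appeared in the read shares (21.8% ± 0.165 of reads at 23–24 nt, n = 2, against 20.2% ± 0.576, n = 4, exact p = 0.0667). Of the 21 nt sequences 1390 were higher and 618 lower. TCCCAGGTACAAGAACACAGC and AGGTACAAGAACACAGCTCAC, both 21 nt and overlapping those lost in dcl3, had no read in nrpe1a against 180 ± 72.3 and 71.9 ± 25.5 RPM in rdr6 (at least 2043-fold and 814-fold lower, adjusted p = 5.5e-04 and 5.1e-04). The 23 nt sequence CAGGTACAAGAACACAGCTCACC had 1 read in nrpe1a and 244 ± 91.0 RPM in rdr6 (adjusted p = 1.0e-10). Whether the mutation or a difference between lines left these gaps was not tested. Among sequences clearly present or missing in every library, 83 were present (at least 5 RPM) in both nrpe1a libraries alone. From these libraries alone 11 were missing (at most 0.1 RPM). Another 64 were present in, and 44 missing from, these and dcl3 1I and 1J alone. The miR156 family, which targets SBP transcription factor transcripts, fell by 2.37 ± 0.45 (log2, SE) from 3142 ± 1567 to 609 ± 151 RPM (adjusted p = 4.3e-04).

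In total 3610 sequences were lower and 5192 higher in nrpe1a. The 23–24 nt group was called higher (camera adjusted p = 0.0027), which did not hold (adjusted p = 0.127 with an estimated correlation). By fry it shifted up (adjusted p = 9.5e-04). At 21 nt camera made no call (adjusted p = 0.292) and fry found a shift up (adjusted p = 9.7e-04), the sign of the mean (0.30) but not of the median (-0.13). The 8802 calls became 5651 with DESeq2, 13664 with every sample as its own replicate, 5691 without library 1O, 5723 without 1P and 14754 with dcl4 as comparator, where 8099 were higher and 6655 lower. The order of the 23–24 nt counts turned in several of these, with 1030 lower and 1136 higher without 1O and 2093 and 3652 with dcl4 as comparator. With DESeq2 1266 were lower and 855 higher at 23–24 nt, and 381 and 938 at 21 nt.

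The comparison of dcl4 with rdr6 set side by side the genotypes known for trans-acting siRNAs, and called 2212 sequences lower and 2138 higher. This was the fewest of the 8 comparisons in this fit. It was not with DESeq2, where dcl4 had 8894 calls and nrpe1a 5651, nor without rdr6 library 1K, where dcl4 had 9463 and nrpe1a at most 8829 in any leave-one-out fit. Of the 23–24 nt sequences 580 were lower and 343 higher, and of the 21 nt sequences 284 were lower and 522 higher. The miR156 family was lower in dcl4 by 3.07 ± 0.47 (log2 change -3.07, SE), at 373 ± 67.4 (n = 2) against 3142 ± 1567 RPM (n = 4, adjusted p = 5.9e-05). The miR408 family, known to target transcripts of copper proteins, was higher by 5.02 ± 0.99, at 66.8 ± 25.05 against 2.03 ± 0.375 RPM (adjusted p = 0.0020). The miR171, miR529, miR534 and miR535 families were also called lower, by log2 changes of -1.45, -2.01, -1.98 and -2.22. The trans-acting siRNA of TAS3 that targets ARF transcripts could not be compared, because the core sequence searched for had 4 reads in all libraries together. A form with another core would not have been counted, so the 4 reads do not give its level in moss.

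These directions depended on scaling and on single libraries. With TMM factors 2076 sequences were lower and 5090 higher in dcl4, with scaling to conserved miRNA reads 365 and 1680, and with DESeq2 3716 and 5178. At 23–24 nt the lower and higher counts became 500 and 899, 81 and 250, and 899 and 916 under these settings, and at 21 nt 236 and 843, 48 and 503, and 426 and 784. The 23–24 nt group call (camera adjusted p = 0.0233) did not hold against the other sequences (adjusted p = 0.285 with an estimated correlation). By fry it shifted down (adjusted p = 9.5e-04). The 4350 calls became 1610 without library 2E (315 lower, 1295 higher), 1312 without 2F (137 and 1175) and 9463 without rdr6 library 1K (4271 and 5192). At 23–24 nt they turned to 83 lower and 180 higher without 2E and 35 and 163 without 2F, and without 1K were 1286 and 889. At 21 nt they were 38 and 374 without 2E, 18 and 369 without 2F and 539 and 849 without 1K. The miR171, miR529, miR534 and miR535 calls all ended with miRNA scaling, a setting added later for families (adjusted p = 0.45, 0.184, 0.0931 and 0.286), without 2E (0.12, 0.0992, 0.0884 and 0.197) and without 2F (0.434, 0.482, 0.293 and 0.457). TMM ended those of miR171, miR529 and miR535 (0.0615, 0.0636 and 0.0772). Fitting these genotypes alone ended that of miR171 (0.0763), and single rdr6 libraries ended some: 1L for miR529 (0.0765) and miR535 (0.104), 1M for miR171 (0.0519) and miR535 (0.1), and 1N for all but miR534 (0.0781, 0.0618 and 0.0572). Where these calls ended, the log2 changes were still -1.73 to -1.03 for miR171, -2.62 to -1.55 for miR529, -2.23 to -1.61 for miR534 and -2.52 to -1.82 for miR535.

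The mDCL mutant changed 23 and 24 nt RNAs in opposite directions. Against rdr6, 5916 of the 23 nt sequences were lower and 781 higher, while 6011 of the 24 nt sequences were higher and 1917 lower. Overlapping sequences of both lengths were among them: the 23 nt sequence CCCAGGTACAAGAACACAGCTCA fell to 0.254 ± 0.0653 RPM in mDCL from 44.4 ± 18.2 RPM in rdr6 (log2 change -7.41 ± 0.53, SE, n = 4 and 4, adjusted p = 1.5e-10), and the 24 nt sequence CCAGGTACAAGAACACAGCTCACC had 159 ± 16.8 RPM in mDCL and 48.3 ± 16.5 RPM in rdr6. Both sequences were also named for dcl3 above. The miR171 family fell by 1.74 ± 0.30 (log2, SE) from 412 ± 180 to 123 ± 44.8 RPM (adjusted p = 1.2e-04). The miR156 family and miR390, the trigger of TAS3 siRNA production, fell by 1.34 ± 0.33 and 1.13 ± 0.31 (adjusted p = 0.0030 and 0.0065). The miR319 family, which targets TCP and MYB transcripts, rose by 0.95 ± 0.34 from 50218 ± 9929 to 96783 ± 14676 RPM (adjusted p = 0.031), and miR408 rose by 2.49 ± 0.86 from 2.03 to 11.6 ± 5.38 RPM (adjusted p = 0.0268).

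Because of this opposition the 23–24 nt group as a whole was not called by camera (adjusted p = 0.104), while fry found a shift up (adjusted p = 0.0426). The 21 nt group, called higher (camera adjusted p = 0.029) with 2266 sequences higher and 1929 lower, did not hold (adjusted p = 0.0866 with an estimated correlation). It was higher by fry (adjusted p = 1.9e-04). The 23 nt direction held under every scaling, with 4645 lower and 1160 higher under TMM, 7361 and 271 under miRNA scaling and 3381 and 1264 under DESeq2. The 24 nt sequences were 7206 higher and 1198 lower under TMM and 6018 and 847 under DESeq2, but 3182 and 2863 under miRNA scaling. Over all lengths 24463 sequences were lower and 15065 higher, which turned with TMM (16649 lower, 20108 higher) and DESeq2 (11760 and 19807) and not with miRNA scaling (33937 and 6621); at 21 nt the split became 1206 lower and 3025 higher, 808 and 3014, and 2974 and 998. With dcl4 as comparator 23683 were called, 12343 of them higher. The miR156 call ended with DESeq2 (adjusted p = 0.054) and miR390 with TMM and DESeq2 (0.0599 and 0.126). The miR319 call ended with miRNA scaling, added later for families (adjusted p = 0.284), and without mDCL 1Z (0.0774), mDCL 2B (0.0609), rdr6 1K (0.08), rdr6 1L (0.0693) or rdr6 1M (0.0567). That of miR408 ended with miRNA scaling (0.115) and without mDCL 1Z (0.075), rdr6 1K (0.0722) or rdr6 1L (0.0663). The log2 changes then were -1.05 for miR156, -0.95 and -0.84 for miR390, 0.28 with miRNA scaling and 0.85 to 0.95 without single libraries for miR319, and 1.79 and 2.13 to 2.47 for miR408.

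Against dcl3, the other Dicer-like mutant with 4 libraries, mDCL held far more 24 nt RNA: 14084 of the tested 24 nt sequences (65.8%) were higher in mDCL and 2608 lower. CCAGGTACAAGAACACAGCTCACC had 159 ± 16.8 RPM in mDCL and no read in dcl3, at least 1885-fold more (adjusted p = 2.5e-13), and TGAGCTGTGTTCTTGTACCTGGGA had 417 ± 78.7 RPM against 1 read (adjusted p = 1.5e-14). Both are among the overlapping or complementary sequences named for dcl3 above and are no separate example. At 23 nt 4487 sequences were higher and 2612 lower. The 20 nt sequence ATATACAACCGATACAGGAG was lower in mDCL, with 3 reads (0.0421 ± 0.0301 RPM) against 11.9 ± 6.47 RPM (adjusted p = 5.2e-11). The miR533 family was lower by 1.66 (log2 change -1.66 ± 0.35, SE), at 143 ± 15.7 against 451 ± 129 RPM (adjusted p = 3.8e-04), and miR171 by -1.02 ± 0.30 (adjusted p = 0.0057).

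As a group, 23–24 nt sequences were higher in mDCL than in dcl3 (camera adjusted p = 5.4e-22; adjusted p = 5.4e-05 with an estimated correlation). The 24 nt split stayed with 14756 higher and 1577 lower under TMM, 13636 and 3338 under miRNA scaling and 14448 and 1362 under DESeq2; at 23 nt it was 5678 and 1498, 3681 and 3314, and 5257 and 1286. Over all lengths 28508 were higher and 28882 lower, an order that also turned when single libraries were left out, and which became 38204 and 16995 under TMM, 22317 and 37159 under miRNA scaling and 37177 and 13928 under DESeq2. Without dcl3 1I and 1J 32322 were called, 21088 of them higher, and at 21 nt 1326 were higher and 1467 lower. TMM and DESeq2 ended the miR171 call (log2 change -0.53 and -0.45, adjusted p = 0.214 and 0.351). The miR408 and miR477 families were called higher over all features (1.99 ± 0.83, adjusted p = 0.0481, and 0.89 ± 0.34, adjusted p = 0.0295), but not when adjusted over the list alone (0.0684 and 0.0563) and not without 1I and 1J (log2 change 1.13 and 0.34, adjusted p = 0.377 and 0.46).

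The last comparison set nrpd1 against nrpe1a, and it contrasts polymerases IV and V only if the titles name these subunits. In nrpd1 9055 of the tested 24 nt sequences were lower than in nrpe1a and 303 higher, and 6185 of the 23 nt sequences were lower and 357 higher. The 21 nt sequences were lower in 3333 cases and higher in 682. TCCCAGGTACAAGAACACAGC and TTGAAGGCCGAGGAGAACATC, both 21 nt, had 85.7 ± 41.6 and 78.0 ± 34.3 RPM in nrpd1 (n = 2) and no read in nrpe1a (n = 2), at least 971-fold and 883-fold more (adjusted p = 7.6e-04 and 2.6e-04). The first is the sequence also missing from nrpe1a against rdr6 above, and the cause of that gap was not tested. The miR156 and miR171 families were higher in nrpd1 by 1.91 ± 0.47 and 1.32 ± 0.42 (log2, SE, adjusted p = 0.0033 and 0.021), and miR533 was lower by -1.61 ± 0.50 (adjusted p = 0.0176).

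As a group, 23–24 nt sequences were lower in nrpd1 than in nrpe1a (camera adjusted p = 1.1e-21; adjusted p = 5.4e-05 with an estimated correlation), with 22737 sequences of all lengths lower and 3970 higher. The 21 nt group was not called by camera (adjusted p = 0.672), while fry found a shift down (adjusted p = 4.7e-06). The 26707 calls became 16832 without nrpd1 1S and 13093 without 1T. At 21 nt 1562 were then lower and 488 higher without 1S and 1246 and 341 without 1T, and at 23–24 nt 8336 and 318 without 1T. The miR156 call ended with TMM, DESeq2 and without 1T (adjusted p = 0.0532, 0.0723 and 0.0707). That of miR171 ended with TMM, miRNA scaling (added later for families), DESeq2 and without 1O, 1P, 1S or 1T (0.247, 0.245, 0.365, 0.101, 0.109, 0.0558 and 0.105), and that of miR533 without 1O or 1S (0.0927 and 0.266). The log2 changes then were 1.47 to 1.53 for miR156, 0.87 to 1.41 for miR171 and -1.44 and -1.11 for miR533.

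**Figure D2:**
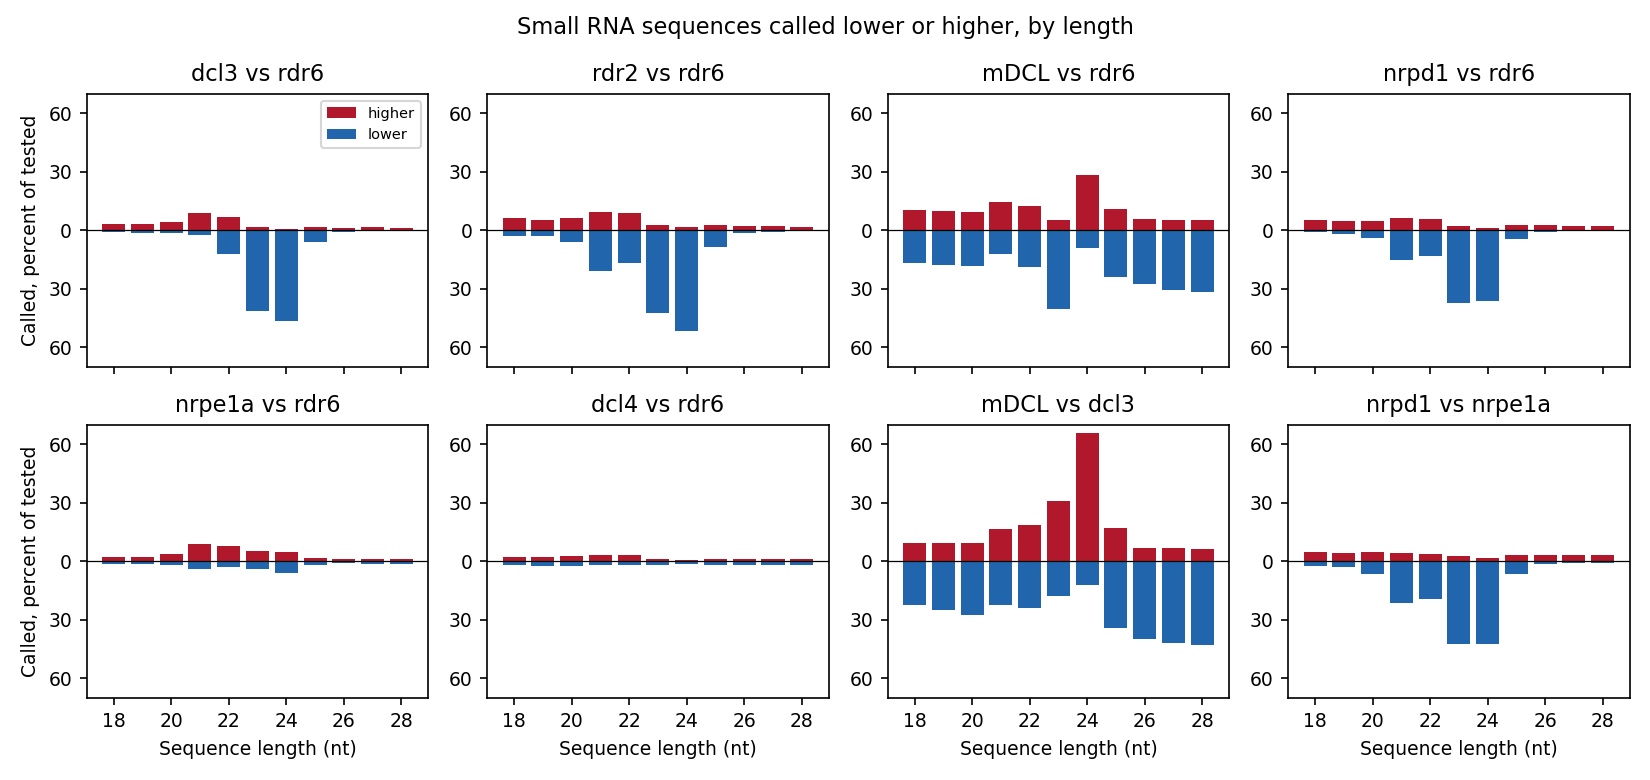
Percent of tested sequences of each length (18 to 28 nt) called higher (red, upward) or lower (blue, downward) in the first genotype of each of the 8 comparisons. In dcl3, 46.6% of the 24 nt sequences were lower than in rdr6, while mDCL had 28.1% of them higher and 40.5% of the 23 nt sequences lower.

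Some of the sequences named as higher than in rdr6 recurred between genotypes. This holds among the printed ones only, which had to be seen in at least 3 genotypes. Larger rises in dcl3, mDCL, nrpe1a and dcl4 belong to sequences not printed. These comparisons share the 4 rdr6 libraries, so a sequence missing from rdr6 alone is higher in each of them. Among sequences clearly present or missing in every library, 63 were present in all 18 libraries outside rdr6 and missing from rdr6. For sequences with no read in rdr6, the recurrence thus reflects that absence and is no repeated, independent result. AGAGCACCGGATGAAGCACTCA (22 nt) had no read in the 4 rdr6 libraries and reached 144 ± 62.9 RPM in dcl3 (n = 4), 172 ± 36.0 in rdr2 (n = 4), 155 ± 42.9 in nrpd1 (n = 2), 246 ± 37.1 in dcl4 (n = 2) and 890 ± 56.8 in nrpe1a (n = 2), from at least 1451-fold to at least 8993-fold more (adjusted p from 1.3e-15 to 9.6e-14). AAGAGCACCGGATGAAGCACTCA (23 nt) was at least 1365-fold, 1257-fold and 4193-fold higher in rdr2, nrpd1 and nrpe1a (adjusted p = 1.8e-13, 5.4e-13 and 1.9e-14). TCCGGTGCTCTTCTACTGCCT and CAGTAGAAGAGCACCGGATGA, both 21 nt, had 113 ± 41.96 and 131 ± 48.8 RPM in dcl3, 82.0 ± 25.4 and 106 ± 12.3 in rdr2, and 82.2 ± 24.5 and 98.2 ± 29.0 in nrpd1, with no read in rdr6. In mDCL, CACTGCAGCTCTGCCTCGGGC (21 nt) had 156 ± 12.1 RPM and none in rdr6, at least 1572-fold more (adjusted p = 4.5e-13). With dcl4 in place of rdr6 as comparator, 12 of the sequences named as higher in dcl3, rdr2 and nrpd1 turned to a lower value, by at most 1.10 on the log2 scale.

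The conserved miRNA families made up 8.77% ± 3.01 (SD, n = 22) of 18–28 nt reads, most of it miR319 with 6.46%. Of 16 families in the list 13 were tested; miR167 had 23 reads, miR396 47 and miR395 0 in all libraries together, the last of which allows up to 0.0117 RPM. Over all features, and adjusted over the list alone, 1 family was higher and 0 lower in dcl3 against rdr6, 1 and 1 in rdr2, 1 and 0 in nrpd1, 0 and 1 in nrpe1a, and 1 and 5 in dcl4. In mDCL against rdr6 the count was 2 higher and 3 lower over all features and 4 higher and 3 lower adjusted over the list alone, which added miR477 and miR533. Between nrpd1 and nrpe1a it was 2 and 1 both ways, and between mDCL and dcl3 it was 2 and 2 over all features and 0 and 2 adjusted over the list alone. The 296 sequences of these families, taken as a group, were called higher in dcl3, rdr2, nrpd1 and between nrpd1 and nrpe1a (camera adjusted p = 2.9e-04, 4.1e-07, 0.0133 and 5.3e-04) and lower in nrpe1a and dcl4 (0.0491 and 3.0e-04); with an estimated correlation none held (adjusted p = 0.641, 0.578, 0.730, 0.641, 0.759 and 0.641). None of the 8 was called by fry (smallest adjusted p = 0.178). In nrpd1 the group's median of -0.04 and mean of -0.02 were opposite in sign to the test.

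**Figure D3:**
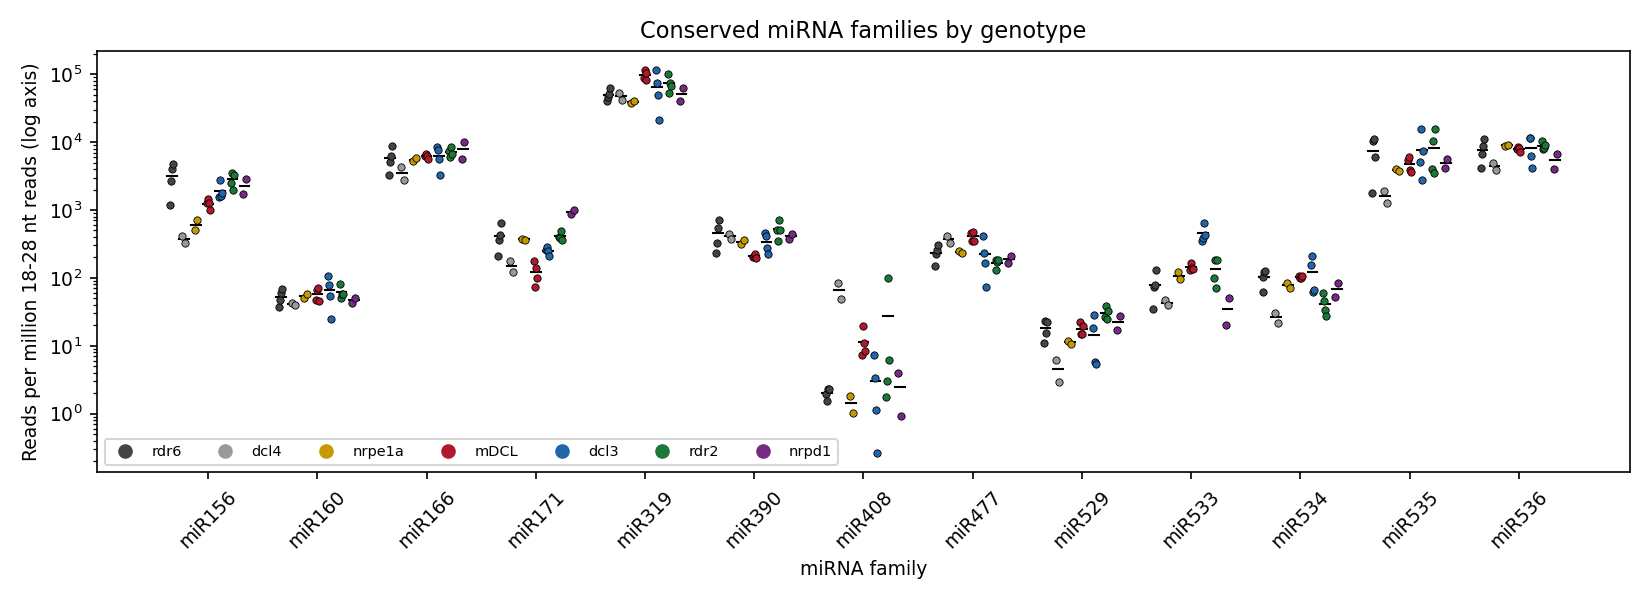
RPM (log axis) of the 13 tested miRNA families in each library (points) with genotype means (bars), in the genotype order of the legend. The dcl3 points lie above all others in miR533, with a mean of 451 RPM, and miR408 was highest in rdr2 library 1E at 99.8 RPM and in dcl4 at 84.5 and 49.1 RPM.

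Sequences of the remaining lengths, fixed as a group of 65956, were called higher relative to the rest in dcl3, rdr2 and nrpd1 against rdr6 (camera adjusted p = 2.3e-13, 1.5e-13 and 2.4e-14; adjusted p = 0.0286 each with an estimated correlation) and in nrpd1 against nrpe1a (adjusted p = 0.0189 with an estimated correlation), and lower in mDCL against dcl3 (adjusted p = 0.0286 with an estimated correlation). In rdr2 their median of -0.09 and mean of -0.11, and in nrpd1 their mean of -0.10, were opposite in sign to the test. The rest is mostly the 36035 sequences of 23–24 nt. Their mean log2 change was -2.68, -2.86 and -2.98 in dcl3, rdr2 and nrpd1 against rdr6. It was -3.03 in nrpd1 against nrpe1a and 2.72 in mDCL against dcl3. These calls thus mirror those of the 23–24 nt group and are no separate result. In mDCL and nrpe1a against rdr6 they were called lower (camera adjusted p = 0.0141 and 0.0021), which did not hold (adjusted p = 0.522 and 0.474 with an estimated correlation). By fry none of the 8 was called (smallest adjusted p = 0.118). The 24 sequences that matched tRNA or rRNA, a mark of RNA breakdown, were called in 1 comparison. This was nrpd1 against nrpe1a (higher, camera adjusted p = 0.0491), which did not hold (adjusted p = 0.581 with an estimated correlation). By fry none was called (smallest adjusted p = 0.304). These tests do not show equal breakdown between genotypes. Of reads of all lengths, chloroplast tRNA-Glu took 4.55% ± 2.45 (n = 2) in nrpd1 and 10.7% ± 1.09 (n = 2) in nrpe1a, opposite to that call. In the other genotypes its mean ran from 5.30% (dcl4) to 10.5% (rdr2). These shares were not tested.

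Other scalings moved the median log2 change of all sequences as follows, and the changes above are relative to that. TMM factors moved it by -0.21 in dcl3, 0.26 in mDCL, -0.17 in nrpd1, 0.26 in nrpe1a and 0.19 in dcl4 against rdr6, by 0.50 in mDCL against dcl3 and by -0.36 in nrpd1 against nrpe1a. Scaling to conserved miRNA reads moved it by -0.54 in rdr2, -0.69 in mDCL, 0.26 in nrpe1a and 0.32 in dcl4, and by -0.62 and -0.17 in the last pair of comparisons. DESeq2 moved it by -0.12 in dcl3, 0.11 in rdr2, 0.42 in mDCL, 0.40 in nrpe1a, and by 0.56 and -0.39 in the last pair.

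Small RNAs also matched hph, the hygromycin resistance gene used as a selection marker for transgenic moss, a set looked at only after the data were seen. They reached 1071 ± 559 RPM in rdr2 (SD, n = 4), 1029 ± 82.3 in nrpe1a (n = 2), 231 ± 91.8 in nrpd1 (n = 2), 113 ± 134 in dcl3 (n = 4) and 80.3 ± 54.0 in mDCL (n = 4). In rdr6 they had 5 reads in 4 libraries (0.178 ± 0.109 RPM) and in dcl4 2 reads in 2 libraries. Within dcl3, libraries 1I and 1J had 285 and 155 RPM and libraries 1G and 1H had 6.5 and 5.67. Of the 369 tested hph sequences, 367 were higher in rdr2 than in rdr6, 359 in nrpe1a, 161 in nrpd1, 102 in dcl3 and 58 in mDCL. As a group they were higher in rdr2 and nrpe1a (adjusted p = 0.0286 and 0.0287 with an estimated correlation), while the calls in dcl3, mDCL and nrpd1 did not hold (adjusted p = 0.522, 0.641 and 0.308 with an estimated correlation). The calls by fry were in rdr2, nrpe1a and nrpd1 (adjusted p = 1.7e-06, 1.0e-05 and 0.0193) and not in dcl3 or mDCL (0.183 and 0.266). Between nrpd1 and nrpe1a 87 hph sequences were lower and 0 higher in nrpd1 in edgeR, and the group was called lower by camera (adjusted p = 2.7e-14; 0.522 with an estimated correlation) and by fry (adjusted p = 0.0062). In dcl4 against rdr6 and mDCL against dcl3 neither test called it (camera adjusted p = 0.104 and 0.108, fry adjusted p = 0.998 and 0.908).

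**Figure D4:**
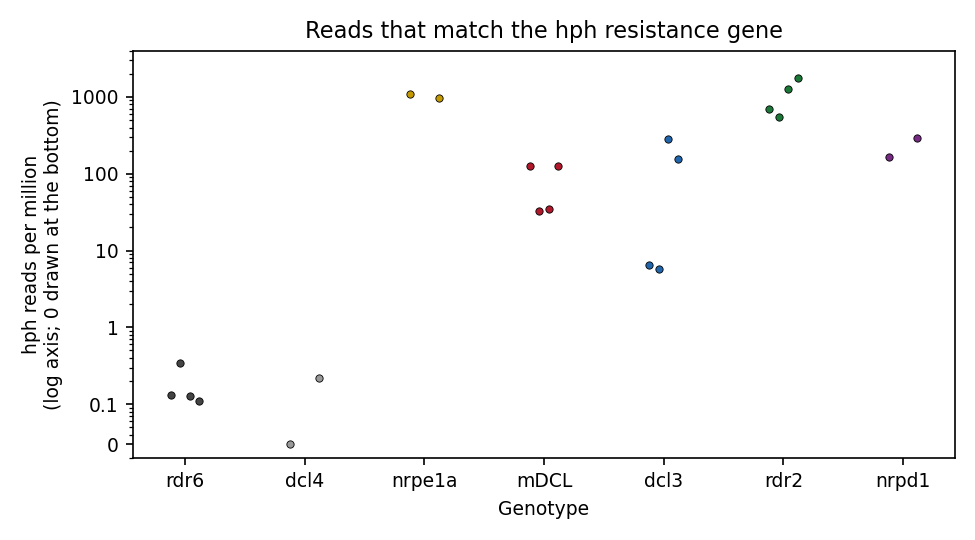
Reads that match the hph resistance gene, in RPM (log axis, with a library at 0 drawn at the bottom), in each library of the 7 genotypes. The rdr6 and dcl4 libraries lie at or below 0.340 RPM and the other 16 at or above 5.67 RPM.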

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

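The tests of hph strand, hph depth, loss of RDR6 and DCL4 products, RNA of a flowering plant and a scaling effect were chosen only after the result was seen, and so were the settings that leave out dcl3 1I and 1J.

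Small RNAs that match the hph resistance gene lie outside the planned comparisons and reached 1763 RPM in a rdr2 library, against at most 0.340 RPM in rdr6. Library 1L was picked out among the rdr6 libraries at that level (the others had 0.111 to 0.131 RPM), but this is 2 reads against 1 in each of the others, all under the floor of 3 reads, and shows no difference. Breakdown of the hph transcript is argued against by the strand and length of the reads, 39.4% of which were antisense and 87.6% 21 or 22 nt long. Low depth is argued against by the 172 reads expected in rdr6 at the lowest level of the other genotypes, of which 5 were seen. A biological explanation, that all lines carry the cassette and its siRNAs need RDR6 and DCL4, cannot be told apart from rdr6 and dcl4 lines without hph, since the highest level there, 0.340 RPM, would be the same under both and the labels do not name the markers.

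A set of sequences divided dcl3 libraries 1I and 1J, together with both nrpe1a libraries, from all others: 64 were present (at least 5 RPM) in these 4 alone and 44 were missing (at most 0.1 RPM) from these 4 alone. Mislabelling of 1I and 1J as nrpe1a libraries is argued against by the 24 nt sequences low in dcl3 1G and 1H, which were low in both too (median log2 ratio to rdr6 at most -5.28) and not in nrpe1a (0.56 to 0.57). An exchange with rdr2 or nrpd1 libraries could not be tested this way. There too 24 nt sequences were lower than in rdr6 (median log2 change -3.74 and -4.01). Strain variants of the same small RNAs cannot be told apart from related small RNAs of 1 family: 4.69% of the 64 sequences (3) had a partner with a 1-base difference among the 44, which both would give. None of 1280 random draws of matching length had one, which decides nothing, because unrelated sequences hardly ever lie 1 base apart. The other sequences of the set had no such partner. No biological explanation was tested, because the labels give no line or background.

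The miR408 family had 99.8 RPM in rdr2 library 1E, far from the other rdr2 libraries (1.73 to 6.08 RPM) and near dcl4 (84.5 and 49.1 RPM), and 24 sequences were present in these 3 libraries alone. Mislabelling of 1E as a dcl4 library is argued against by the 24 nt sequences low in the other rdr2 libraries, which were low in 1E as well (median log2 ratio to rdr6 -5.53) and much less so in dcl4 (-0.70 to -0.24). An exchange with a dcl3 or nrpd1 library could not be tested this way, since 24 nt sequences were lower in these too (median log2 change -3.70 and -4.01). RNA of a flowering plant is argued against by miR167 and miR396, common in such plants, which reached at most 1.32% of the miR408 level, and a scaling effect by the 12 other families, whose median ratio to the other 19 libraries was at most 1.02. Copper supply, growth conditions and another source of RNA were not tested and stay open.

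The 20 nt share was 9.50% in rdr6 library 1N, far from the other rdr6 libraries (9.21% to 9.25%). Reads outside 18–28 nt, not used in the comparisons, made up 43.0% to 54.1% of the reads of a library, and chloroplast tRNA-Glu alone took 2.82% to 13.5% of all reads. Of 84 groups of 4 libraries looked at for a library far from the others, 3 had one, that of hph in rdr6 among them, while chance gives about 1 in 20 (4.2).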

How the results depend on the processing

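The settings without hph sequences, without dcl3 1I and 1J and without rdr2 1E and rdr6 1K, and for miRNA families also miRNA scaling, no filter and every sample as its own replicate, were chosen only after the data were seen. Of 4188 values under an alternative (280 results), 441 of 524 counts of called sequences stayed within 1.5 times, 99 of 126 counts of called families did, and 1275 of 1306 named sequences, 1518 of 1630 single families and 542 of 602 length shares kept direction and side of the threshold; 169 values past the threshold in neither setting changed sign. Only Apr runs, only the genotypes compared and removal of hph sequences moved no total count of called sequences beyond 1.5 times. Where a value moved, the cause was not tested, except that leaving libraries out leaves fewer samples. In leave-one-out fits that leave 1 library of a genotype, it is assumed to vary like the other groups. Reads split over several places, reads that match the genome and TAS3 tests under any setting were not run. No paired analysis was possible because library codes do not pair genotypes. In simulated data with the real depths and means, edgeR recovered 0 of 67 2-fold changes in each of 3 comparisons. DESeq2 recovered 1 of 67 for dcl3 against rdr6. The simulation changed 200 sequences, while the real comparisons called from 4350 (dcl4 against rdr6) to 57390 (mDCL against dcl3). The adjustment was thus stricter in the simulation, and its recovery is no measure of the power of the real fits. These called some changes under 2-fold, such as miR319 in mDCL against rdr6 (log2 change 0.95, adjusted p = 0.031). How many real changes of that size were missed was not tested, so the absence of a call does not exclude them. Whether depth, spread or the number of libraries limits recovery was not tested.

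Total calls moved as follows, and with DESeq2, and without rdr6 1K, nrpe1a took the place of dcl4 as the comparison with the fewest. For dcl4 against rdr6 (4350) they were 7166 with TMM, 2045 with miRNA scaling, 7381 with every sample as its own replicate, 8894 with DESeq2, 10808 without rdr2 1E and rdr6 1K, and 1312 to 9463 in leave-one-out. For nrpe1a against rdr6 (8802) they were 13664 with every sample as its own replicate, 14754 with dcl4 as comparator, 5651 with DESeq2 and 5691 to 8829 in leave-one-out. For rdr2 they were 51774 with no filter, for mDCL 23683 with dcl4 as comparator, for nrpd1 8327 to 21994 in leave-one-out, and for nrpd1 against nrpe1a 13093 to 21735 in leave-one-out. Without dcl3 1I and 1J they were 14021 for dcl3 against rdr6 and 32322 for mDCL against dcl3.

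The number of called miRNA families moved with TMM to 2 in dcl3 (from 1), 3 in dcl4 (from 6) and 1 in nrpd1 against nrpe1a (from 3); with DESeq2 to 1 in rdr2 (from 2), 0 in nrpd1 (from 1) and 1 in nrpd1 against nrpe1a. With DESeq2 the nrpd1 count of 0 replaces miR171 at an adjusted p of 0.197. With miRNA scaling it was 3 in mDCL (from 5) and 2 in dcl4; with every sample as its own replicate 2 in dcl3 and 2 in nrpd1; without rdr2 1E and rdr6 1K 3 in dcl3, 1 in rdr2 and 2 in nrpd1; and with only the genotypes compared 0 in nrpd1. In leave-one-out it ranged from 1 to 3 in dcl3, 3 to 7 in mDCL, 0 to 2 in nrpd1, 2 to 6 in dcl4, 2 to 5 in mDCL against dcl3 and 1 to 2 in nrpd1 against nrpe1a.

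With dcl4 in place of rdr6, 12 named sequences changed direction: 4 of dcl3 to -0.78, -0.40, -0.14 and -0.64 (log2), the first and the last 3 of rdr2 to -0.52, -0.44, -0.067 and -1.10, and 4 of nrpd1 to -0.67, -0.017, -0.55 and -1.10.

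Length shares (differences in percentage points or in the ratio, exact permutation p in brackets) changed as follows. The 23–24 nt difference of dcl3 against rdr6 was -6.12 (0.114) over 20–24 nt reads, -5.90 (0.0667) without dcl3 1I and 1J, -3.86 (0.0571) without rdr2 1E and rdr6 1K and -4.93 to -3.42 in leave-one-out. That of rdr2 was -3.60 (0.1) without rdr2 1E and rdr6 1K. That of mDCL against rdr6 was -0.246 (0.857) by distinct sequences and -1.26 to -0.801 in leave-one-out, and that of mDCL against dcl3 was 1.89 (0.4) over 20–24 nt reads, 4.88 (0.0667) without dcl3 1I and 1J and 2.4 to 3.91 in leave-one-out. The ratio difference became 0.0631 in dcl3 and 0.0442 in rdr2 by distinct sequences (0.0286 each), 0.273 to 0.434 in leave-one-out in rdr2, and -0.862 (0.0667) in mDCL against dcl3 without 1I and 1J. By distinct sequences the 22 nt difference of mDCL turned to -0.490 against rdr6 and -0.406 against dcl3, and against dcl3 the 21 nt one to -2.36 and the 23 nt one to 1.23 (exact p = 0.0286 each).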

Other observations

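The test of whether the rdr6-low sequences need DCL4 was chosen only after the result was seen; the splits of libraries and the test of shared 5′ ends were not.

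Among 6108 abundant sequences of 21 or 22 nt, from which those that match hph had been removed, 425 were nearly absent from rdr6, 259 of 21 nt and 166 of 22 nt. They took 6.29% of 18–28 nt reads in nrpe1a, 1.04% in mDCL and 0.0033% in rdr6, and 71.8% of them had a complementary duplex partner among the reads, against 8.87% of the 5683 others. RDR6 is known to copy cleaved transcripts into double-stranded RNA, and such sequences could be its products. If so, they might need DCL4 too: 20.2% of them (86) were at 10% or less of their expected reads in dcl4, against 2.87% of the others (163), and their median level in dcl4 was 0.758 of that expected. This does not decide between products that other Dicer-like enzymes also cut and sequences missing from the rdr6 line for other reasons, since dcl4 and rdr6 had 2 and 4 libraries and their lines are not described.

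The first base of 23 nt reads was C in 58.2% ± 5.68 (SD, n = 4) of reads in rdr6, 61.6% ± 3.93 (n = 4) in dcl3, 63.4% ± 0.979 (n = 4) in mDCL and 67.3% ± 1.48 (n = 4) in rdr2. At 24 nt C made up 25.5% ± 1.66 of reads in rdr6, 30.8% ± 0.674 in dcl3, 32.9% ± 1.72 in mDCL, 30.8% ± 0.672 in rdr2 and 23.4% ± 0.261 (n = 2) in nrpe1a, where A made up 33.4% ± 0.168. Among distinct 23 nt sequences C began 20.04% ± 0.524 in rdr6 and 24.5% ± 0.192 in mDCL. These differences were not tested.

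The fall of 23 nt and rise of 24 nt RNA in mDCL might come from a change of length at the same 5′ end. Over 7294 pairs of sequences that share their first 23 nt, the ratio of 23 to 24 nt reads was 3.43 ± 0.0969 in mDCL (n = 4) and 4.91 ± 1.54 in rdr6 (n = 4), a factor of 1.43 (exact permutation p = 0.114). The ratio was lower in mDCL in 66.9% of pairs. A change of length at the same end and independent changes of both classes cannot be told apart, since the rdr6 libraries ranged from 3.33 to 6.69.

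In the 4 comparisons with 4 libraries per genotype, the other splits of the 8 libraries into 4 and 4 were fitted as well. The real split, 1 of 35, gave the most calls in each: 20750 for dcl3 against rdr6, 28203 for rdr2 against rdr6, 39819 for mDCL against rdr6 and 59344 for mDCL against dcl3, with 0 as the highest of the other splits in edgeR. This share is the smallest that 35 splits allow, and 3 of the 4 comparisons share the rdr6 libraries. Chance is an unlikely source of each lead taken singly, but it is not excluded. The splits cannot tell genotype from line or culture, which libraries of 1 label may share. The other splits mix the genotypes within each group, which widens the spread there, so the 0 is no measure of false calls. At an unadjusted p under 0.05 the real splits had 28133, 35264, 51995 and 66112 sequences and the highest of the others 24635, 12553, 16851 and 15119. DESeq2 was not run on the splits.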
